A study of Mus musculus with 16 samples.

How the data were processed

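The series holds RNA-seq counts for cortical bone from the tibiae of 8 male mice aged 16 weeks, 4 labelled Ctrl and 4 labelled NT3-Cre+ (NT3 in these texts). The series title places the study in mice with NF-kB inducing kinase (NIK, encoded by Map3k14) switched on in bone-forming cells. Per the labels, the right tibia was compressed axially on 9 days at 1200 cycles per day and the left tibia was the non-loaded partner. Peak force was 8.7 N in Ctrl and 10.0 N in NT3, chosen to reach the same strain of -2000 microstrain. Bones were taken 4 hours after the last bout, stripped of muscle and flushed of marrow by centrifugation. The mean RNA integrity number given was 5.4. The allele behind the NT3 label, the Cre driver and the genotype of the Ctrl mice were not given in the sources used here.

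Libraries were made from total RNA depleted of ribosomal RNA, primed with random primers and sequenced single-end for 75 bases. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.4.2a, counted with featureCounts 1.4.6 of Subread and tested with DESeq2. The values per the labels were gene counts made by the authors, and the integers in the files fitted that unit. The annotation release and the strand setting of the counting were not given in the sources used here. Of 47517 rows, 45250 matched the GENCODE annotation by symbol and 611 by an older symbol. The matched rows held 86.1% of the fragments, and 87.3% of the unmatched fragments were in the Rn18s-rs5 and Gm20417 rows.

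Each row was placed on GRCm38 and compared with the exons of genes on the other strand. A row was called opposite a gene where their exons overlapped by at least 20 bases. This naming was chosen after the values had been seen. Rows are given by their own name, followed where their values are first given by the genes they lie opposite. Rows with Gm, Rik or clone names were also named after the values had been seen, because of the gene on the other strand.

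The comparisons were set before the data were examined: NT3 against Ctrl in non-loaded tibiae, NT3 against Ctrl in loaded tibiae, loaded against non-loaded in Ctrl, the same in NT3, and the difference between these loading effects. Genotype comparisons used 8 libraries of separate mice. Loading comparisons and their difference used all 16 libraries with a replicate block for mouse. The pairing came from the design text, which names both limbs of each mouse. It was checked by correlating the deviations of the limbs from their group means, which gave 0.045 to 0.178 within mice. Only for Ctrl mouse 4 did another mouse give a higher value, 0.157 against 0.045.

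Rows were filtered with filterByExpr at a minimum count of 10, scaled by TMM and tested with robust edgeR quasi-likelihood F tests. Adjusted p values are Benjamini-Hochberg values over the rows tested in a comparison, and a row was called at adjusted p < 0.05. Log2 fold changes are given with their standard error (SE), and TMM-scaled counts per 1e+06 fragments (CPM) as mean ± SD of 4 libraries. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and statmod 1.5.0. Correlation p values come from exact permutation.

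Gene groups were tested with camera at a preset correlation of 0.01 on those of 26 lists drawn up beforehand that had at least 3 tested rows. These were 16 or 20 lists by row name, as planned, and 10 to 12 by the gene on the other strand. Every called list was retested with an estimated correlation. The counts of called members are given over all rows tested, and again after adjustment over the list alone.

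Named rows were chosen by rule: the 12 smallest adjusted p values in each direction with a mean of at least 20 fragments. Each NT3 limb also had to lie on the same side of the Ctrl mean, or each mouse to move the same way with loading. For the difference in loading response, the mean change had to run in opposite directions in the genotypes. Where fewer than 5 rows were called in a direction, the 5 smallest p values were taken. Up to 4 members of a called list, 2 of other lists, and 14 rows fixed in advance from the subject of the study were added. The fixed rows were those of Map3k14, Nfkb2, Relb, Sost, Dmp1, Col1a1, Bglap, Postn, Wnt1, Wnt7b, Tnfsf11, Tnfrsf11b, Acp5 and Ctsk.

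The tests were also tested on simulated data with 200 changed rows in each comparison. In non-loaded and loaded genotype comparisons, 51% and 62% of 2-fold changes were recovered, and 95% of 4-fold changes in each. For loading, the shares were 46% in Ctrl and 59% in NT3 at 2-fold, with 98% and 90% at 4-fold. For the difference between loading effects, they were 21% and 74%. Between 5 and 11 unchanged rows were called in each simulation.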

Results

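Cortical bone from 16 tibiae was compared between 4 Ctrl and 4 NT3 mice, each with a loaded right and a non-loaded left limb. Libraries held 897909 to 998031 counted fragments in non-loaded Ctrl, 852831 to 1064391 in loaded Ctrl, 775531 to 961382 in non-loaded NT3 and 758394 to 911686 in loaded NT3. Ribosomal RNA rows took 13.9 ± 2.80%, 14.8 ± 2.10%, 10.7 ± 3.34% and 13.7 ± 3.12% of these groups in that order (mean ± SD, n = 4). The Gm10800 row, which holds satellite-like repeats, took 0.132% to 5.72% of a library. The Rabep2 row, opposite the fast-muscle calcium pump gene Atp2a1, ran from 329 to 4144 CPM.

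Many abundant rows lay over exons of a gene on the other strand. Of 1242 matched rows averaging at least 100 fragments, 1093 (88.0%) did so, against 6813 of 44619 other rows (15.3%). Rows of usually abundant transcripts were low: Actb held 11 to 33 fragments per library, Gapdh, opposite Iffo1, 23 to 51 and the haemoglobin row Hbb-bs 0 to 9. The 79 ribosomal protein rows together held 0.0819% of the fragments. The files do not separate the fragments of a row from those of the gene opposite, so both names are given. The value of a row may therefore not measure the gene it is named for.

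Map3k14, which encodes NIK, held 1 to 9 fragments per library and did not pass the filter on low counts. Per 1e+06 counted fragments, without TMM scaling, it had 2.64 ± 1.84 in non-loaded Ctrl and 5.29 ± 2.94 in non-loaded NT3 (mean ± SD, n = 4), and 3.88 ± 2.24 and 6.40 ± 4.77 after loading. In an edgeR fit without the filter, the NT3 to Ctrl log2 fold change was 0.85 in non-loaded limbs (adjusted p = 0.651) and 0.62 in loaded limbs (adjusted p = 0.753). The genotype labels could not be checked from these counts. Among the other fixed rows, Relb, Bglap, Tnfsf11, Tnfrsf11b, Acp5, Ctsk, Wnt1, Wnt7b and Postn also held too few fragments to test, with at most 18 in any library.

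In non-loaded tibiae, the Tbc1d17 row, opposite Akt1s1 and Il4i1, an amino acid oxidase of antigen-presenting cells, was 3.62-fold higher in NT3 than in Ctrl (290 ± 52.3 against 79.3 ± 16.6 CPM; log2 1.86, SE 0.18, adjusted p = 2.7e-07). The Zmynd15 row, opposite the chemokine gene Cxcl16, rose by 1.77 log2 units (SE 0.21, adjusted p = 1.1e-05). The Dexi row, opposite the class II regulator Ciita, rose by 1.27 (SE 0.18, adjusted p = 1.4e-04), and the Fzd2 row, named for a Wnt receptor, fell by 2.52 (SE 0.34, adjusted p = 5.3e-05).

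Also higher in non-loaded NT3 limbs were the rows of Prune2 (1.48), Nrp1 (1.73), Nxpe4 (1.30), Tesk1, opposite the B cell gene Cd72 (1.057), and Art3, opposite the chemokine gene Cxcl10 (1.56). The Oraov1 row, opposite the cyclin D1 gene Ccnd1, rose by 0.85 and the Rfc2 row, opposite the adaptor gene Lat2, by 0.79. Rows named after the values had been seen were D030025P21Rik, opposite Ltbp2 (1.90, adjusted p = 1.4e-06), Gm29439, opposite Cd22 (1.12, adjusted p = 0.011), and Psd, opposite Nfkb2 (0.81, adjusted p = 0.019). Nfkb2 encodes the precursor that NIK signalling has cleaved. The Nfkb2 row itself, opposite Psd and AC114539.1, held 8 to 22 fragments per library and did not pass (0.26, adjusted p = 0.93). Lower in NT3 were the rows of Ddx4 (-1.34), Numb, opposite Gm46367 (-1.22), Vps13b, opposite Gm48960 and Cox6c (-1.04), and Tg, opposite Gm17140 (-1.21). The fixed rows of Sost (-0.81, adjusted p = 0.48), Dmp1 (-0.25, adjusted p = 0.89) and Col1a1 (0.21, adjusted p = 0.97) did not pass.

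Across the non-loaded genotype comparison, 36 of 6220 rows were called by edgeR, 26 higher and 10 lower in NT3, with 486 at unadjusted p < 0.05. None of the 16 lists tested by row name was called; the osteoblast list had a median of 0.21 (adjusted p = 0.224). By the opposite gene, the NF-kB target list had 2 of 4 rows called higher, and 2 when adjusted over the list alone (median 0.68, camera adjusted p = 1.1e-04; adjusted p = 0.0699 with an estimated correlation). The B lymphoid list had 1 of 3 called higher, and 1 adjusted over the list alone (median 0.35, adjusted p = 0.0031; adjusted p = 0.364 with an estimated correlation). The collagen list had 0 of 7 called, and 0 adjusted over the list alone (median 0.32, adjusted p = 0.0131; adjusted p = 0.460 with an estimated correlation). The edgeR count was 10 with marrow marker rows as a covariate, 77 without Ctrl mouse 1, 12 without Ctrl mouse 2, 20 without Ctrl mouse 3 and 14 without NT3 mouse 3. With the marrow covariate, the median signed log2 change of the 36 called rows was 0.907, against 0.931 without it, and 36 of 36 kept their direction. That median lies among the 26 higher rows and does not measure the 10 lower ones.

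In loaded tibiae, the Tbc1d17 row, opposite Akt1s1 and Il4i1, was 3.99-fold higher in NT3 than in Ctrl (263 ± 51.7 against 65.7 ± 12.4 CPM; log2 2.00, SE 0.17, adjusted p = 1.3e-09). The Zmynd15 row, opposite Cxcl16, rose by 1.91 (SE 0.18, adjusted p = 1.1e-08), and the Psd row, opposite Nfkb2, by 1.18 (SE 0.15, adjusted p = 4.1e-06). The Nt5c3b row, opposite the collagen chaperone gene Fkbp10, fell by 0.79 (SE 0.15, adjusted p = 9.7e-04), and the Fzd2 row by 1.87 (SE 0.37, adjusted p = 0.0020).

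Higher in loaded NT3 limbs were Dexi, opposite Ciita (1.61), Tesk1, opposite Cd72 (1.81), Art3, opposite Cxcl10 (2.73), Nxpe4 (1.85) and Ms4a6c, opposite BE692007 (1.55). The Rfc2 row, opposite Lat2, rose by 0.98. After the values had been seen, the rows of D030025P21Rik, opposite Ltbp2 (1.88, adjusted p = 4.1e-11), Gm29439, opposite Cd22 (1.73, adjusted p = 8.8e-08), and Gm16175, opposite the NF-kB family gene Bcl3 (1.45, adjusted p = 0.0034), were added. The same holds for 5730488B01Rik (1.20, adjusted p = 0.0093) and Gm12462 (1.02, adjusted p = 0.017), both opposite the B cell factor gene Pax5.

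Lower in loaded NT3 limbs were Sla (-1.44), Phf20l1 (-1.92), Ddx4 (-1.79), Cobl (-2.21), Rapgef4, opposite Rapgef4os2 (-1.87), Col11a1 (-1.34), Tg, opposite Gm17140 (-1.07), and Numb, opposite Gm46367 (-1.40). Also lower were Bmp3 (-1.11, adjusted p = 0.048) and Ctgf, opposite Gm15270 (-0.94, adjusted p = 0.028). After the values had been seen, rows opposite matrix and growth factor genes were added: Gm38391, opposite Plod2 (-0.82), Gm37804, opposite Tgfb3 (-1.16), and Gm29491, opposite Tgfb2 (-1.10). The fixed rows did not pass: Sost (-1.35, adjusted p = 0.076), Col1a1 (-0.52, adjusted p = 0.11), Dmp1 (-0.39, adjusted p = 0.37) and Nfkb2, opposite Psd and AC114539.1 (0.02).

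The loaded genotype comparison called 161 of 6080 rows, 80 higher and 81 lower in NT3, with 808 at unadjusted p < 0.05. By row name, 4 of 16 lists were called, each lower in NT3. The collagen list had 0 of 14 rows called, and 6 adjusted over the list alone (median -0.68, camera adjusted p = 0.0013; adjusted p = 0.280 with an estimated correlation). The osteocyte list had 0 of 7, and 3 adjusted over the list alone (median -0.64, adjusted p = 0.0088; adjusted p = 0.280 with an estimated correlation). The list of genes known to respond to bone loading had 1 of 11, and 2 adjusted over the list alone (median -0.66, adjusted p = 0.0241; adjusted p = 0.294 with an estimated correlation). The osteoblast list had 2 of 14 lower, and 5 lower and 1 higher adjusted over the list alone (median -0.50, adjusted p = 0.0458; adjusted p = 0.280 with an estimated correlation).

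By the opposite gene, the NF-kB target list in loaded limbs had 3 of 4 rows called higher, and 3 adjusted over the list alone (median 1.32, adjusted p = 2.5e-10; adjusted p = 0.0055 with an estimated correlation). The B lymphoid list had 3 of 3, and 3 adjusted over the list alone (median 1.20, adjusted p = 7.6e-10; adjusted p = 0.0357 with an estimated correlation). The osteoblast list had 1 of 7 lower, and 2 adjusted over the list alone (median -0.44, adjusted p = 2.1e-04; adjusted p = 0.163 with an estimated correlation). The collagen list had 1 of 7 lower, and 1 adjusted over the list alone (median -0.33, adjusted p = 0.0013; adjusted p = 0.228 with an estimated correlation). Skeletal muscle had 0 of 9, and 0 adjusted over the list alone (median -0.93, adjusted p = 0.0013; adjusted p = 0.417 with an estimated correlation). Smooth muscle had 0 of 4, and 1 adjusted over the list alone (median -0.35, adjusted p = 0.0119; adjusted p = 0.124 with an estimated correlation). With mice ranked by animal number as a 2-level term, 64 rows were called in place of 161, of which 60 were shared.

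**Figure D1:**
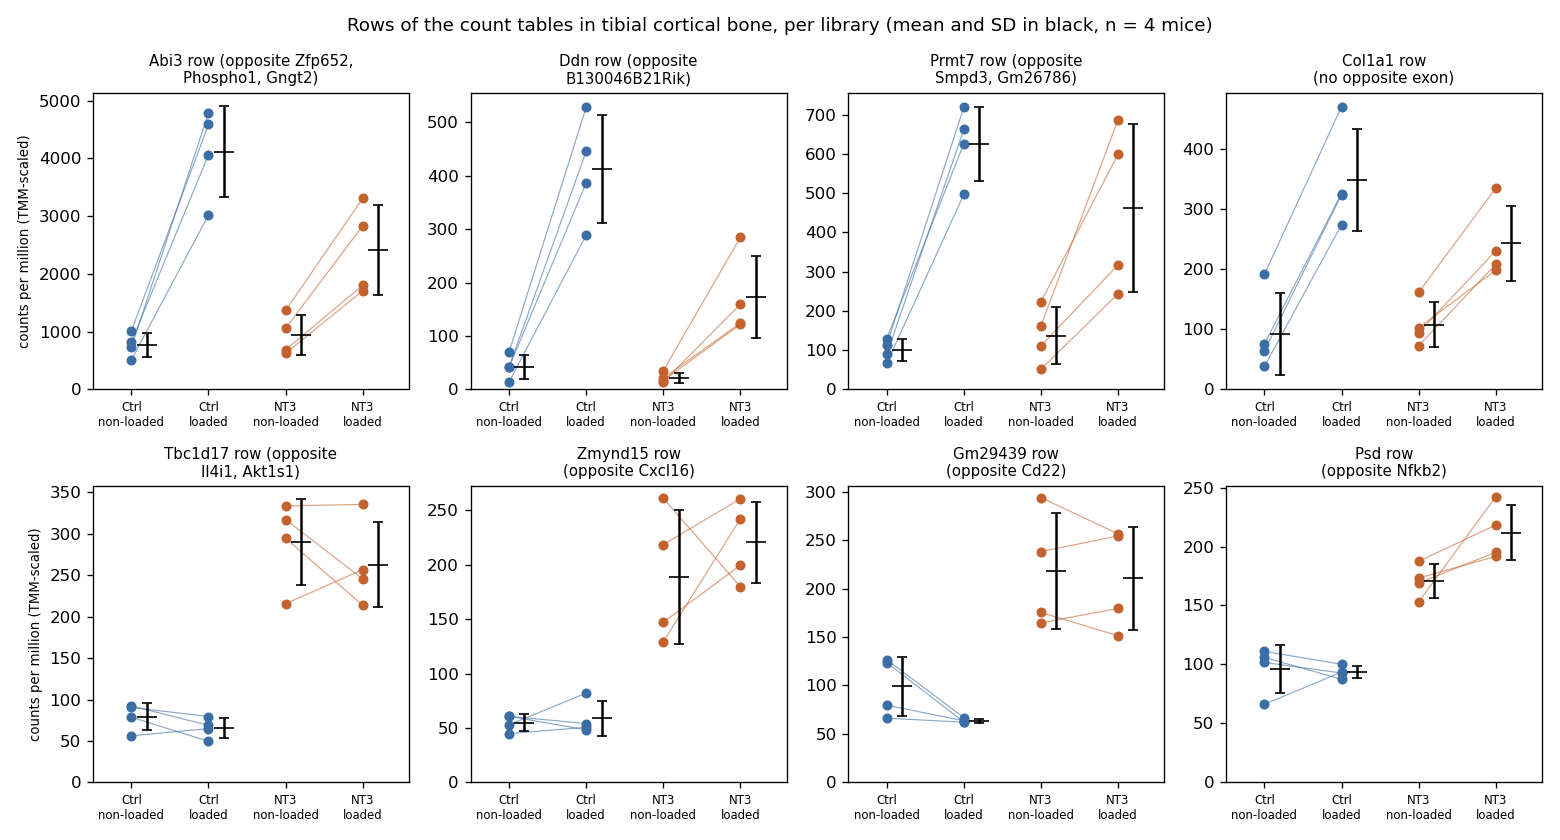
CPM of 8 rows in each tibia, with the limbs of a mouse joined by a line. The title of each panel names the genes whose exons the row overlaps on the other strand.

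The genotype effects in the limbs had 18 higher and 9 lower called rows in common, against 0.36 and 0.133 expected for unrelated calls among 5779 rows tested in both. The shared rows included Tbc1d17, opposite Akt1s1 and Il4i1, Zmynd15, opposite Cxcl16, and Fzd2. The same mice supplied both limbs, so differences between mice enter both sets.

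Loading of Ctrl tibiae raised rows of collagen and osteoblast genes. The Abi3 row, opposite Zfp652, Gngt2 and Phospho1, a phosphatase that starts matrix mineral, rose 5.44-fold (766 ± 208 to 4115 ± 792 CPM; log2 2.44, SE 0.12, adjusted p = 1.0e-20). The Prmt7 row, opposite Gm26786 and the sphingomyelinase gene Smpd3, rose by 2.67 log2 units (SE 0.14, adjusted p = 4.0e-19), and the Ddn row, opposite B130046B21Rik, by 3.37 (SE 0.17, adjusted p = 1.6e-19). The Col1a1 row, named for the main collagen gene of bone, rose 4.18-fold (log2 2.06, SE 0.17, adjusted p = 6.3e-12). The Kcnh7 row, opposite the granulocyte gene Gca, fell by 0.79 (SE 0.13, adjusted p = 5.0e-05).

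Other matrix rows that rose in Ctrl were Col1a2 (1.79), Sparc (1.85), Col11a1 (1.98), Col11a2 (1.54), Col5a1, opposite Gm13372 and 2810430I11Rik (1.37), Col5a2 (1.90), Col6a2 (2.06) and Col3a1 (1.45). The Nt5c3b row, opposite Fkbp10, rose by 1.63 (adjusted p = 2.6e-14), Prkag1, opposite B130046B21Rik, by 3.04, H2-Pb by 4.07, Slc15a3, opposite Tmem132a, by 1.15 and Mterf2, opposite Tmem263, by 1.34. Ibsp, bone sialoprotein, rose by 0.99 (adjusted p = 1.5e-05), the osteocyte gene Dmp1 by 0.72 (adjusted p = 0.0045) and the connexin gene Gja1 by 1.97 (adjusted p = 0.015). Rows named after the values had been seen were 2810430I11Rik (2.07) and Gm13372 (1.96), both opposite Col5a1, Chn1os3, opposite Chn1 (1.83), 1700051A21Rik, opposite the citrate transporter gene Slc13a5 (2.24), and Gm38391, opposite Plod2 (1.15). Sost, whose product restrains bone formation, did not pass (-0.40, adjusted p = 0.64).

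Rows that fell with loading in Ctrl, chosen by the rule, included Hps3, opposite the ceruloplasmin gene Cp (-0.66), Cerkl, opposite the integrin gene Itga4 (-0.62), Adgrg3 (-0.85), Tctn1, opposite Gm15481 and Hvcn1 (-0.50), Hcn3, opposite the red cell enzyme gene Pklr (-1.04), Krr1, opposite Glipr1 (-0.51), Ly6e (-1.19), Cr2 (-0.75), Hsd11b1 (-1.23) and Ankrd11, opposite Gm45894 (-0.53). Gm11505, opposite the granule gene Mpo, was added after the values had been seen (-0.75, adjusted p = 0.043).

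Loading in Ctrl called 293 of 7192 rows, 221 higher and 72 lower, with 1061 at unadjusted p < 0.05. By row name, 3 of 20 lists were called: osteoblast, with 4 of 14 higher and 5 adjusted over the list alone (median 0.20, mean 0.58, adjusted p = 7.8e-08), collagens, with 6 of 18 and 9 adjusted over the list alone (median 0.89, adjusted p = 9.0e-08), and chondrocyte, with 2 of 4 and 2 adjusted over the list alone (median 0.74, adjusted p = 0.0063; adjusted p = 0.129 with an estimated correlation). By the opposite gene, the osteoblast list had 5 of 7 higher and 6 adjusted over the list alone (median 1.19, adjusted p = 1.9e-32), and collagens 6 of 7 and 6 adjusted over the list alone (median 0.87, adjusted p = 4.7e-25). The Wnt list had 1 of 6 higher and 1 adjusted over the list alone (median 0.51, adjusted p = 0.0057; adjusted p = 0.0727 with an estimated correlation). Tendon had 1 of 3 higher and 2 adjusted over the list alone (median 0.51, adjusted p = 0.0057; adjusted p = 0.124 with an estimated correlation). Smooth muscle had 1 of 4 higher and 2 adjusted over the list alone (median 0.37, adjusted p = 0.010; adjusted p = 0.136 with an estimated correlation). B lymphoid had 2 of 3 lower and 2 adjusted over the list alone (median -0.60, adjusted p = 0.010; adjusted p = 0.162 with an estimated correlation). The count was 171 without the replicate block for mouse, 163 without Ctrl mouse 2, 188 without Ctrl mouse 3, 126 and 128 with the Gm10800 and Gm11505 rows as covariates, and 81 (70 shared) with the mean of marrow marker rows as a covariate. That mean was lower in the loaded limb of each of the 8 mice, at 2.43 to 2.54 log2 CPM in non-loaded Ctrl against 2.32 to 2.38 in loaded Ctrl. With it as a covariate, the median log2 change of the 293 called rows was 0.786, against 0.785 without it, and 292 kept their direction. With the Gm10800 and Gm11505 rows the medians were 0.799 and 0.812. These medians are of signed values over rising and falling rows together. They lie among the rising rows and do not measure the falling ones. With marrow marker rows as a covariate, 66 higher and 15 lower rows were called, against 221 and 72 in the main fit.

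In NT3 tibiae, leading rows of the Ctrl loading comparison also rose with loading. The Abi3 row, opposite Zfp652, Phospho1 and Gngt2, rose 2.62-fold (933 ± 346 to 2412 ± 786 CPM; log2 1.39, SE 0.11, adjusted p = 1.7e-12). The Prmt7 row, opposite Smpd3 and Gm26786, rose by 1.79 (SE 0.14, adjusted p = 1.1e-12), the Ddn row, opposite B130046B21Rik, by 2.98 (SE 0.20, adjusted p = 6.9e-15) and Col1a1 by 1.19 (SE 0.16, adjusted p = 1.5e-05). The Sphk2 row, opposite Rpl18 and the clock gene Dbp, fell by 0.56 (SE 0.13, adjusted p = 0.028).

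Further rows that rose in NT3 were Prkag1, opposite B130046B21Rik (2.53), H2-Pb (2.09), Col11a2 (1.68), Aph1b (4.16), Nt5c3b, opposite Fkbp10 (0.71), and Mterf2, opposite Tmem263 (0.80). Those added after the values had been seen were 2810430I11Rik (0.96) and Gm13372 (0.90), both opposite Col5a1, and Chn1os3, opposite Chn1 (0.73). The Caprin1 row fell by 1.19 (adjusted p = 0.047), and Gm15441, opposite Txnip, by 0.49 (adjusted p = 0.025). Col1a2 (0.65, adjusted p = 0.11), Dmp1 (0.59, adjusted p = 0.17) and Sost (-0.91, adjusted p = 0.63) did not pass.

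Loading in NT3 called 30 of 7192 rows, 24 higher and 6 lower, with 546 at unadjusted p < 0.05. By row name, only the chondrocyte list of the 20 tested was called, with 1 of 4 higher and 2 adjusted over the list alone (median 0.46, adjusted p = 0.0096; adjusted p = 0.318 with an estimated correlation). By the opposite gene, the osteoblast list had 4 of 7 higher and 5 adjusted over the list alone (median 0.80, adjusted p = 3.1e-22). Collagens had 2 of 7 higher, and 4 higher and 1 lower adjusted over the list alone (median 0.40, adjusted p = 5.8e-06; adjusted p = 0.0542 with an estimated correlation). The Wnt list had 0 of 6, and 2 adjusted over the list alone (median 0.52, adjusted p = 0.0016; adjusted p = 0.0542 with an estimated correlation). Skeletal muscle had 0 of 9, and 0 adjusted over the list alone (median -0.68, adjusted p = 6.8e-07; adjusted p = 0.311 with an estimated correlation). Without the replicate block, 5 rows were called, limma-voom called 4, and 10 were called with marrow marker rows as a covariate. The median signed log2 change of the 30 rows was 0.874, 0.870 and 0.791 in these fits, against 0.866 in the main fit. It lies among the 24 higher rows and does not measure the 6 lower ones. In each, 30 of 30 kept their direction. The count was 17 without NT3 mouse 1.

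The response to loading was called smaller in NT3 than in Ctrl for 10 rows and larger for none of the 7192 tested. Another split of the mice called 11 rows, so chance was not excluded. In simulated data, 21% of 2-fold differences of this kind were recovered, so rows not called may still differ. Ibsp, the only called row to meet the naming rule, differed by -1.10 log2 units (SE 0.22, adjusted p = 0.012), from 102 ± 32.7 to 202 ± 65.2 CPM in Ctrl and from 123 ± 24.1 to 115 ± 30.9 in NT3. After the values had been seen, the other called rows were added, led by Abi3, opposite Zfp652, Phospho1 and Gngt2 (-1.056, SE 0.16, adjusted p = 1.6e-04), and Gm20444, opposite C1qtnf5 and Mfrp (-1.61, SE 0.24, adjusted p = 1.6e-04). Matrix rows among them were 2810430I11Rik (-1.10) and Gm13372 (-1.07), both opposite Col5a1, Nt5c3b, opposite Fkbp10 (-0.92), and Col1a2 (-1.13). The others were Gm26840, opposite Vwa1 (-1.63), Chn1os3, opposite Chn1 (-1.11), and Prmt7, opposite Smpd3 and Gm26786 (-0.88).

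Col1a1 (-0.87, adjusted p = 0.17), Sparc (-1.21, adjusted p = 0.22), Sost (-0.51, adjusted p = 0.95) and Dmp1 (-0.13, adjusted p = 0.97) did not pass for the difference in loading response. Nor did the smallest p values on the higher side, Tesk1, opposite Cd72 (0.76, adjusted p = 0.28), and Ppm1e (0.86, adjusted p = 0.30). By row name, 2 of 20 lists were called lower: osteoblast, with 2 of 14 and 4 adjusted over the list alone (median -0.57, adjusted p = 1.7e-04; adjusted p = 0.0729 with an estimated correlation), and collagens, with 0 of 18 and 1 adjusted over the list alone (median -0.73, adjusted p = 7.9e-04; adjusted p = 0.0729 with an estimated correlation). By the opposite gene, collagens had 2 of 7 lower and 6 adjusted over the list alone (median -0.73, adjusted p = 8.5e-13), and osteoblast 2 of 7 and 3 adjusted over the list alone (median -0.38, adjusted p = 3.0e-06). The B lymphoid list lay on the other side, with 0 of 3 and 3 higher adjusted over the list alone (median 0.75, adjusted p = 0.0013; adjusted p = 0.127 with an estimated correlation). NF-kB targets had 0 of 4 and 0 adjusted over the list alone (median 0.62, adjusted p = 0.0040; adjusted p = 0.0750 with an estimated correlation). Also called lower by the opposite gene, but not with an estimated correlation, were skeletal muscle (median -0.86, 0 of 9 and 0 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation), bone loading response (median -0.32, 0 of 4 and 2 adjusted over the list alone, adjusted p = 0.193 with an estimated correlation), tendon (median -0.34, 0 of 3 and 1 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation) and smooth muscle (median -0.36, 0 of 4 and 0 adjusted over the list alone, adjusted p = 0.186 with an estimated correlation). Without the replicate block, edgeR called 0 rows, with 335 at unadjusted p < 0.05. The limma-voom fit called 0, with 466 at unadjusted p < 0.05, and DESeq2 called 10.

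**Figure D2:**
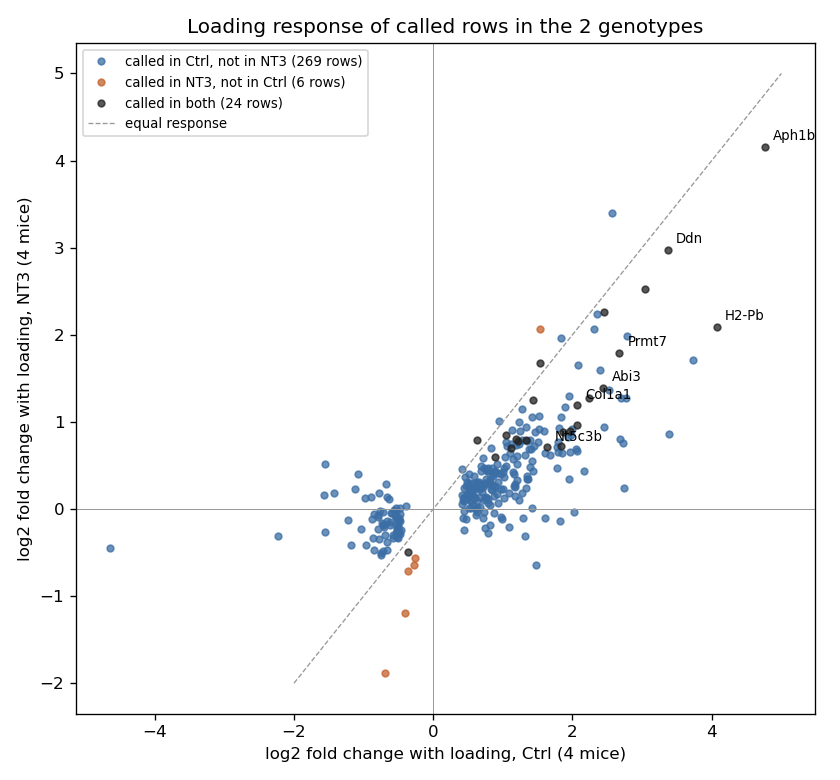
Log2 fold change with loading in Ctrl and in NT3 for the rows called in either genotype. Picking rows by a call in Ctrl favours large values in Ctrl.

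The loading effects shared 23 higher rows, Abi3, Ddn, Prmt7 and Col1a1 among them, against 0.737 expected for unrelated calls, and 1 lower row against 0.0601. In the 24 shared rows the median size was 1.85 log2 units in Ctrl and 0.93 in NT3, and 21 were larger in Ctrl. Among the 30 rows called in NT3, a choice that favours NT3, the medians were 1.53 in Ctrl and 0.93 in NT3. The rows larger in Ctrl there were the same 21, and none of the 6 rows called only in NT3 was larger in Ctrl. Over the tested rows, the loading effects of the genotypes, which share no mouse, correlated at r = 0.319 (rank correlation 0.226).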

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

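The tests of fragment number, of overlap on the same strand, of opposite-strand overlap and of marrow rows were chosen only after the result was seen, as were the alternatives with Gm10800, animal number and muscle-opposite rows. Each of 364 groups of 4 libraries was examined for a library standing apart from the other 3, and 11 (3.02%) did. Chance gives about 1 in 20 for independent values. Of the 91 measures, 83 were rows named in the text, many chosen for moving the same way in each limb. The share therefore does not show that the libraries are free of outliers.

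The libraries standing apart were these, with the range of the other 3 of their group. For the share of ribosomal RNA rows, NT3 loaded 1 had 9.11% (14.8% to 15.9%), and for the Gm10800 row Ctrl non-loaded 2 had 3.28% (0.132% to 0.308%). In CPM, Ctrl non-loaded 2 had 21.3 for Art3 (9.81 to 11.5), Ctrl loaded 2 had 148 for Rfc2 (203 to 207) and Ctrl loaded 4 had 33.9 for Numb (50.7 to 52.5). NT3 loaded 3 had 29.4 for Bmp3 (13.6 to 16.1), Ctrl non-loaded 3 had 45.1 for Ctgf (59.5 to 60.8) and NT3 non-loaded 3 had 40.0 for Gm16175 (23.2 to 25.7). NT3 loaded 2 had 101 for Prkag1 (28.1 to 38.3), and Ctrl non-loaded 4 had 12.8 for Col6a2 (6.87 to 7.85) and 170 for Hps3 (231 to 237). No library was left out of the fits for this.

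Rows called for a loading response that differed by genotype were Abi3 (-1.056), Gm20444 (-1.61), 2810430I11Rik (-1.10), Gm13372 (-1.07), Gm26840 (-1.63), Nt5c3b (-0.92), Ibsp (-1.10), Chn1os3 (-1.11), Col1a2 (-1.13) and Prmt7 (-0.88). The lists called by row name were osteoblast (-0.57) and collagens (-0.73), each with adjusted p = 0.0729 with an estimated correlation, where neither was called; fry called 0 lists.

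Exchanging labels between mice gave 35 splits for each genotype comparison. In non-loaded limbs chance cannot be excluded: the real split called 36 rows and the highest other 40. That other split set Ctrl mice 1, 2 and 3 and NT3 mouse 1, which carry the lower animal numbers, against the rest. With a term for animal number, 39 rows were called between genotypes in non-loaded limbs, of which 24 were among the 36. In loaded limbs the real split called 161 rows, against 2 in the highest other split. Its share of 0.0286 is the smallest that 35 splits can give. It lay under 0.05, without adjustment over the comparisons. For the difference in loading response chance was not excluded, with 10 rows against 11. For loading within a genotype, the 8 exchanges of limbs are too few for a share under 0.05; the real counts were 293 in Ctrl and 30 in NT3, against 0 in the highest other split of each.

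Abundant rows lay over exons of genes on the other strand more often than other rows did, with an odds ratio of 40.7 (95% interval 34.2 to 48.4). Sharing of fragments by overlapping genes whatever their strand was excluded, as the odds ratio for overlap on the same strand was 1.26 (interval 1.00 to 1.58), and few fragments per library would lower rows alike, whereas protein-coding rows with an opposite exon held 11.9 times the median of those without an opposite gene (5.94 against 0.5), a value that restates the pattern. Rows opposite ribosomal protein genes held 3.59 times the fragments per overlapping base of rows opposite other genes (bootstrap 0.0963 to 12.8), which alone decides nothing. Counting against the strand of the gene would give the odds ratio of 40.7 and the low Actb, Hbb-bs and ribosomal protein rows. It remains a candidate not tested directly, and whether the kit marked strand was not given in the sources used here. If it holds, values by row name do not measure the named genes. This includes Col1a1, Ibsp, Dmp1, Sost, Map3k14 and the marrow marker rows. Counting the same reads in both strand settings would decide between these readings.

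Rows opposite NF-kB and B lymphoid genes were higher in loaded NT3 limbs. Rows opposite erythroid or neutrophil markers differed by -0.29 (Apex2, opposite Alas2 and Pfkfb1), -0.0479 (Plppr3, opposite Prtn3 and Ptbp1, the median) and 0.25 (Gm11505, opposite Mpo, SE 0.17). The B lymphoid rows rose by 1.02 to 1.73, which argues against an even carry-over of marrow as the whole cause. Marrow richer in B lymphoid cells was not excluded, as these 3 marker rows do not measure it, and Apex2 and Plppr3 also lie opposite other genes. Repeat content was excluded as the whole cause, because 6 of 6 rows stayed called with the Gm10800 covariate. With the 2-level animal number term in the fit, a share of 0.882 of the median effect stayed (1.33 before, 1.17 with a median SE of 0.30 after). This argues against that split as the whole cause, though only 3 of 6 rows were still called. The term departs from genotype only in Ctrl mouse 4 and NT3 mouse 1, so finer differences between animals were not excluded. More B lymphocytes in NT3 bone could not be told from more transcript per cell, as the list had 3 rows. Staining of the cortical shaft for B lymphocytes would tell these apart.

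Loading called fewer rows in NT3, and the 10 rows called for the difference responded less there. Fragment number was excluded, as thinning each library to the smallest left 286 calls in Ctrl against 27 in NT3, a ratio of 10.6, and muscle was excluded as the whole cause, as a share of 0.932 of the median difference stayed with rows opposite muscle genes as a covariate (-1.10 with a median SE of 0.21 before, -1.03 with 0.23 after), though only 5 of the 10 rows were still called. Higher levels before loading in NT3 would leave the loaded limbs alike. For the rows higher with loading in both genotypes, the loaded limbs argue against this as the whole cause, but the test did not exclude it. Their median NT3 to Ctrl difference in non-loaded limbs was 0.0948 log2 units, and 14 of 20 were higher in NT3. That median met its bound set beforehand, but by less than the SE of the mean over mice. The mean over mice there was uncertain, at 0.10 (SE 0.23). In loaded limbs 21 of 23 were lower in NT3, and the mean over mice was -0.59 (SE 0.19). The loaded median of -0.47 passed its bound, 0.3 lower, but also by less than that SE. Other rows were not covered by this test. Peak force went with genotype in the 2 combinations used, 8.7 N in Ctrl and 10.0 N in NT3, so it could not be separated from genotype. Loading both genotypes at both forces would separate them.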

How the results depend on the processing

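The alternatives with Gm10800, Gm11505, animal number, muscle-opposite rows, opposite-strand lists and paired omission of mice were tests chosen only after the result was seen. Counts here are called rows; values within 1.5-fold of the reported one are left out, and where no cause is given the cause was not tested. None of the named called rows reversed in sign under these alternatives. The median log2 changes of the called rows with marrow marker rows as a covariate are given in the results above.

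For genotype in non-loaded limbs (36), the count was 71 with no filter, 10 with marrow marker rows as a covariate, 171 with both limbs summed and 58 with Gm10800 as a covariate. It was 20 without Ctrl 2 and NT3 4, the mice with the highest Gm10800 share in a limb. NT3 4 reached its highest share, 5.72%, in the loaded limb. Among non-loaded NT3 limbs, mouse 2 was highest (2.33% against 0.948% in mouse 4), and it stayed in that fit. Leaving out 1 mouse gave 12 to 77.

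For genotype in loaded limbs (161), it was 64 with animal number, 98 with Gm11505 as a covariate and 106 without Ctrl 2 and NT3 4. Leaving out 1 mouse gave 119 to 201.

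For loading in Ctrl (293), it was 169 with DESeq2, 81 with marrow marker rows, 171 with no replicate block, 126 with Gm10800, 128 with Gm11505 and 193 without Ctrl 2 and NT3 4. Leaving out 1 mouse gave 163 to 325.

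For loading in NT3 (30), it was 19 with DESeq2, 4 with limma-voom, 18 with robust=FALSE, 10 with marrow marker rows, 5 with no replicate block and 19 with rows opposite muscle genes as a covariate. Leaving out 1 mouse gave 17 to 44.

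For the difference in loading response (10), it was 17 with no filter, 0 with limma-voom (466 at unadjusted p < 0.05; DESeq2 called 10), 0 with no replicate block, 5 with rows opposite muscle genes, 19 with Gm11505 and 16 without Ctrl 4 and NT3 4, the mice highest in muscle rows. Leaving out 1 mouse gave 7 to 14.

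The number of called lists in loaded limbs (4) was 0 with an estimated correlation, 1 with fry, the endothelial list (higher in NT3), which is none of the 4, and 2 by the opposite gene with an estimated correlation, NF-kB targets and B lymphoid. By the opposite gene it was 3 in non-loaded limbs (0 by row name), 6 for loading in Ctrl (3), 4 for loading in NT3 (1) and 8 for the difference in response (2). With an estimated correlation, these opposite-gene counts became 0, 2, 1 and 2. Loading in NT3 gave 0 with an estimated correlation, 0 with fry and 3 with rows free of opposite exons. The difference in response gave 0 with an estimated correlation and 0 with fry.

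Among values of named called rows under the alternatives, those that lost the call were 52 against 356 kept in non-loaded limbs, 15 against 561 in loaded limbs, 58 against 517 for loading in Ctrl, 68 against 249 for loading in NT3 and 54 against 166 for the difference in response.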

Other observations

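The tests of the Tg locus and the groups of rows described here were chosen only after the result was seen.

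For several rows that rose with loading and had no protein-coding exon opposite, the nearest gene ending toward them on the other strand was looked up. No distance limit or background rows were used, so a neighbour is found whatever the row and the placement decides nothing. Ddn and Prkag1 also lie opposite exons of B130046B21Rik, by 177 and 950 bases. Ddn and Prkag1 lay 9940 and 18960 bases beyond the end of Wnt1, H2-Pb lay 7077 bases beyond Col11a2 and Aph1b lay 8357 bases beyond Car12. Their rises in Ctrl were 3.37, 3.04, 4.07 and 4.76 log2 units, while the Wnt1 row itself held 0 to 13 fragments per library. Extl1, also looked up, lay 1888 bases beyond Slc30a2. Wnt1 drives bone formation, and Car12 is a carbonic anhydrase, but whether their transcripts reach these rows was not tested.

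The Ube2c row, named for a cell cycle gene and opposite the fast-muscle troponin gene Tnnc2, followed the Rabep2 row, opposite Atp2a1, across the 8 non-loaded limbs (r = 0.994, exact p = 2.5e-05, BH-adjusted 1.5e-04 over 12 relations; without the 2 farthest mice, 0.986). With the Mki67 row, of another cell cycle gene, r was 0.716 in non-loaded limbs (exact p = 0.0465, BH-adjusted 0.0929), turning to -0.518 without the 2 farthest mice, and -0.396 in loaded limbs (-0.295 without them).

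Of the rows lower in loaded NT3 limbs, Phf20l1, Tg, Gm17140 and Sla start within 203300 bases of each other on chromosome 15. In random draws of as many called rows from those tested, as many rows fell in a span as short in a share of 0.0014 (13 of 10000 draws, with the real set added to both numbers). Their log2 differences in loaded limbs were -1.92, -1.07, -1.91 and -1.44. The draws treat rows as independent and were run on the cluster that prompted them, while Sla and Gm17140 overlap Tg, so the share decides nothing.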
